A study of Mus musculus with 6 samples.

How the data were processed

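Single-cell RNA sequencing was analysed for 6 libraries of mouse cardiac fibroblasts that had been sorted on the mEFSK marker after transverse aortic constriction (TAC), a surgical narrowing of the aorta that overloads the left ventricle. Going by their titles, 3 libraries came from wild-type (WT) hearts and 3 from hearts with a deletion of Il1b (here titled Il1b-KO). The deletion was made in cells that express Cx3cr1, which the titles do not state. Each library was deposited as a matrix of raw counts of unique molecular identifiers (UMIs) per gene and barcode, with a gene list and a barcode list. Per the submitters' processing notes, CASAVA 1.8, Cell Ranger 5 and Seurat 3 were used with the mm10 mouse genome, without a statement of which step each tool served. Filters applied by the authors before deposit are not given in the sources used here. Raw counts in the files were whole numbers whose totals differed between libraries.

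The groups were taken from the titles. The names of the deposited files give the opposite group for 4 of the 6 libraries, so the groups of the report are the titled groups. The split that the file names spell out, 1 of the 10 ways of splitting the 6 libraries into 3 and 3, called many genes and was then examined on its own in the closing section, with the same tests. The labels do not say whether each library came from a separate animal, so p-values measure the spread between these libraries, which may in part be technical. No pair of libraries agreed within sampling noise, and none was treated as a duplicate. For the titled replicate numbers 1, 2 and 3, deviations from the group means correlated at r = 0.57, -0.34 and 0.34 across genes. These deviations also carry the file-name split described in the closing section, which cuts across the titled groups. They therefore cannot decide whether the numbers mark pairs.

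The 6 libraries held 38164 barcodes. Barcodes with at least 500 detected genes and at most 20% mitochondrial UMIs were kept. Gene values are given in CPM, scaled by TMM for single genes in fibroblast-like cells. The automatic threshold of Scrublet (in scanpy 1.11.5) called 0 or 1 doublet per library and was judged not to have worked, so the highest-scoring barcodes were removed instead, at 0.8% per 1000 barcodes (4.27% to 6.05% of a library). The 35803 kept cells were scaled to 10000 UMIs, log-transformed and clustered on 2000 variable genes, 30 principal components and 15 neighbours with the Leiden method at resolution 1, with no batch correction. Clusters of at least 30 cells led by another class than fibroblasts were clustered again at resolution 0.5. A cluster was named for the class with the largest fraction of its markers detected in at least 30% of its cells, and stayed unnamed with fewer than 3 detected markers, with leading genes of another class, or where it was shallow with none of its class's markers among its 10 leading genes. These cutoffs on detection were set after the data were seen, while the markers were fixed before.

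UMIs of fibroblast-like cells were summed per library and tested with the edgeR 4.0.16 quasi-likelihood test (R 4.3.3, robust fit, filterByExpr, TMM scaling, group as the only term), with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists fixed beforehand were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, for lists with at least 3 tested genes, and again with an estimated correlation and with fry. Per-library values, namely Il1b in UMIs per 1000000 UMIs (CPM), shares of cell classes and shares of fibroblast-like cells with a Postn or Meox1 UMI after thinning each cell to 2000 UMIs, were compared by two-sided exact permutation tests. With 3 libraries against 3 the smallest p these tests can give is 0.1. Intervals on single libraries are exact 95% Poisson or Clopper-Pearson intervals and cover counting error only. A count of 0 is given with the level that 3 counts would have.

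The genes named in the text follow a rule fixed before the data were examined. It takes genes that the study is about, the 10 genes of smallest p in each direction (as not passing where fewer than 5 pass, which was the case), and up to 4 genes of smallest p from each list, and it skips predicted, ribosomal protein, haemoglobin, immunoglobulin and sex-chromosome inactivation genes in the genome-wide part. Other genes are named with a statement that they were chosen after their values were seen. Alternatives fixed beforehand were another scaling, weaker and stricter count filters, leaving out each library, the titled replicate number as a block, all kept cells, a stricter cell filter (at least 1000 genes and at most 10% mitochondrial UMIs), no doublet removal, thinning to the smallest library, other thinning depths, clustering at resolution 0.5, DESeq2 1.42.0 and limma-voom. A comparison of the 2 libraries whose title and file name agree was added after the data were seen. Positions are those of GENCODE M21, on the GRCm38 (mm10) assembly.

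The fit was tested on simulated data, with counts drawn for 16312 genes from the means, library sizes and dispersions of the titled comparison and 50 genes changed at each fold. It recovered 2% of genes changed by 1.5-fold, 34% by 2-fold, 86% by 4-fold and 82% by 8-fold, and called 11 of 16112 unchanged genes. Genes were drawn independently, whereas genes of the real libraries move together, so these rates need not hold for the data.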

Results

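Sorted cardiac fibroblasts from pressure-overloaded mouse hearts were profiled in 6 single-cell libraries, 3 titled WT TAC and 3 titled Il1b-KO TAC. The series concerns signalling from immune cells to fibroblasts in the failing heart, and this comparison asks how fibroblasts differ when Il1b, which encodes the inflammatory cytokine interleukin-1 beta, is deleted in Cx3cr1-expressing cells, a population that includes macrophages. The libraries titled WT held 5558, 5375 and 7550 barcodes with 66570226, 58843771 and 86117895 UMIs (replicates 1, 2 and 3). Those titled Il1b-KO held 7566, 6775 and 5340 barcodes with 67941751, 78116128 and 64916061 UMIs. The median UMI count per barcode was lowest in the library titled Il1b-KO 1, at 8386, and between 10403 and 11539 in the others.

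The title and the name of the deposited file disagree on the genotype of 4 of the 6 libraries. They agree only for the libraries titled WT 3 and Il1b-KO 1. The groups below are those of the titles, and each library is called by its title.

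The targeted gene, Il1b (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139), was rare in all 6 libraries. A fibroblast sort mostly removes cells of the deleted lineage, and whether this accounts for the low counts was not tested. Over all kept cells, the libraries titled WT 1, WT 2 and WT 3 held 36, 107 and 11 Il1b UMIs, or 0.573 CPM (UMIs per 1000000 UMIs; 95% Poisson interval 0.402 to 0.794), 1.92 (1.57 to 2.32) and 0.139 (0.0694 to 0.249). The libraries titled Il1b-KO 1, 2 and 3 held 3, 56 and 4 UMIs, or 0.0478 CPM (0.00987 to 0.14), 0.77 (0.582 to 1.0) and 0.0655 (0.0179 to 0.168). The mean was 0.878 ± 0.93 CPM in the titled WT group and 0.295 ± 0.412 in the titled Il1b-KO group (SD, n = 3 each; exact permutation p = 0.5, where the smallest possible is 0.1). The library titled Il1b-KO 2 lay above 2 of the 3 libraries titled WT, and without the library titled WT 2 the difference of the means was -0.0616 CPM in place of -0.584. Nearly all of these UMIs came from the macrophage-like cells, where titled WT 1, 2 and 3 had 325, 839 and 137 Il1b CPM. Titled Il1b-KO 2 and 3 had 224 and 35.6 there, and titled Il1b-KO 1 had 0 of 8787 macrophage-like UMIs, where 3 counts would be 341 CPM (83.4 CPM without doublet removal, at 0 of 35983 UMIs). The labels do not give the deleted exons, and 3' counts outside a deleted part would not show the deletion, so Il1b does not settle the genotype of any library.

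Fibroblast-like cells made up 34959 of the 35803 kept cells. Their share was 97.5% ± 0.482 in the libraries titled WT and 97.8% ± 0.385 in those titled Il1b-KO (SD, n = 3 each; exact permutation p = 0.6). The other named classes were 129 endothelial-like, 103 mural-like, 82 epicardial or mesothelial-like, 49 macrophage-like and 32 Schwann-like cells. A further 449 shallow cells with a median mitochondrial share of 8.61% stayed unnamed. Macrophage-like cells were 7, 8 and 6 of the kept cells in the libraries titled WT 1, 2 and 3, and 2, 15 and 11 in those titled Il1b-KO 1, 2 and 3. The shares were 0.125% ± 0.0367 and 0.161% ± 0.116 (SD, n = 3 each; exact permutation p = 0.6). The sort sets these shares, and the classes were rebuilt from markers.

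In fibroblast-like cells, edgeR called no gene between the titled groups at the threshold, while DESeq2 called 31. Cst6 (ENSMUSG00000024846, chromosome 19, 5344705 to 5349574), which encodes the protease inhibitor cystatin E/M, had the smallest p, with 142 ± 18.2 CPM in the titled Il1b-KO libraries against 61.5 ± 7.68 in the titled WT libraries (log2 difference 1.20, SE 0.14). Zbtb16, a glucocorticoid-responsive transcription factor, was at 170 ± 36.2 against 385 ± 57.3 (log2 difference -1.18, SE 0.19). Atf3, a stress-induced transcription factor, was at 15.8 ± 4.75 against 57.9 ± 23.9 (log2 difference -1.88, SE 0.35). Nfkbiz, an atypical inhibitor of NF-kB that IL-1 signalling induces, was at 95.6 ± 17.6 against 179 ± 32.7 (log2 difference -0.90, SE 0.19). Each of these genes was on the same side in all 3 libraries of a group (SD, n = 3), and each had an adjusted p of 0.437 by edgeR's quasi-likelihood test.

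The other genes of smallest p with higher titled Il1b-KO values had log2 differences from 0.47 for Ergic3 to 1.37 for Mmrn2. Ergic3 and Vps28 serve vesicle transport, Rnasek and Gpr137 act in acidic compartments, Dancr is a long noncoding RNA, and Crlf2 encodes a cytokine receptor. Sh3bgrl3 encodes a small thioredoxin-like protein, Fxyd5 a regulator of the sodium pump and Mmrn2 a vascular matrix protein. Those with lower values had log2 differences from -0.50 for Fgf2, a fibroblast mitogen, to -1.50 for Ntrk2, a neurotrophin receptor. Between them lay the phosphodiesterase Pde10a, the glutamate receptor Gria1, the zinc finger gene Zfp970, the Wnt5a receptor Ror2 and the trafficking regulator Agap1. Mmrn2 and Ntrk2 were faint, at 1.47 ± 0.351 CPM against 0.563 ± 0.143 and 0.643 ± 0.177 against 1.82 ± 0.396. None of the genes listed in this paragraph passed by edgeR. Of 16312 genes tested with edgeR, 0 were called in either direction, 1805 had an unadjusted p under 0.05 (1017 higher and 788 lower), and the lowest adjusted p was 0.437. DESeq2 called 31 genes, 14 higher and 17 lower, and limma-voom called 0. The DESeq2 calls included Cst6, Atf3, Zbtb16, Nfkbiz and Tagln. They also included every gene listed above in this paragraph except Mmrn2 and Ntrk2. The titled groups did not overlap for 2748 genes (16.8%), where a split gives 10% on average. Genes move together, so a single split can lie far from that average, and the share is no test. Over the 10 splits, 61 to 2767 genes had an unadjusted p under 0.05 by edgeR. A split that follows neither titles nor file names had 2738.

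Among the genes the study is about, Postn (ENSMUSG00000027750, chromosome 3, 54361109 to 54391037), which encodes the matrix protein periostin and marks activated fibroblasts, was at 3352 ± 1674 CPM in the titled Il1b-KO libraries and 2539 ± 2072 in the titled WT libraries (SD, n = 3 each), with a log2 difference of 0.40 and an SE of 0.64. Meox1 (ENSMUSG00000001493, chromosome 11, 101877510 to 101894374), a homeobox transcription factor of activated fibroblasts, was at 545 ± 252 and 451 ± 267, with a log2 difference of 0.27 and an SE of 0.53. The spread within each titled group was wider than either difference. The interleukin-1 receptor gene Il1r1 was at 98.1 ± 12.6 against 147 ± 50.7 (log2 difference -0.59, SE 0.24, edgeR adjusted p = 0.437). Its accessory chain Il1rap was at 38.5 ± 7.16 against 44.5 ± 3.8, the bromodomain gene Brd4 at 126 ± 5.73 against 140 ± 5.94, and the NF-kB subunits Rela at 41.4 ± 3.15 against 42.5 ± 5.5 and Nfkb1 at 254 ± 43.7 against 279 ± 13.6. Cx3cr1, the chemokine receptor gene whose lineage carries the deletion, was near 1.97 CPM in both groups, with a log2 difference of 0.0018, an SE of 0.22 and a sign that changed with the scaling. Il1b had 0 to 3 UMIs per library in these cells and was not tested.

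**Figure D1:**
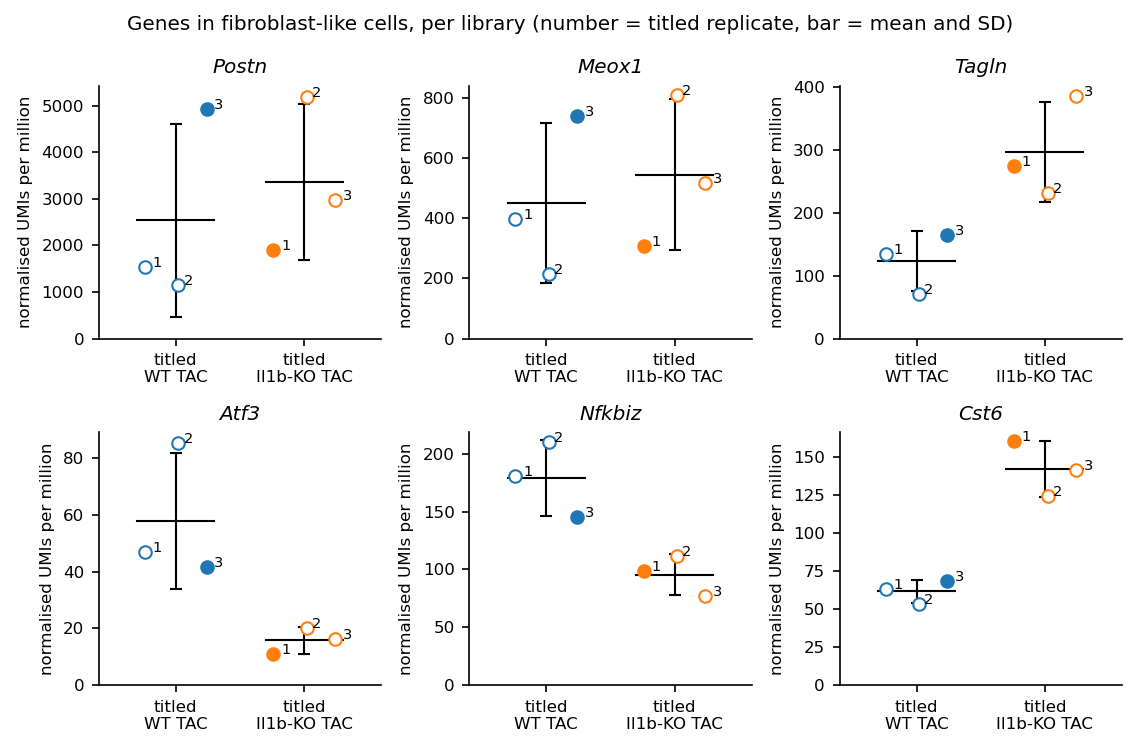
Normalised CPM in fibroblast-like cells (linear axes from 0) for 6 genes, with each point a library, its number the titled replicate, and the bar and whisker the mean and SD of the titled group. Filled points are the 2 libraries whose title and file name agree. Postn and Meox1 values overlap between the titled groups, while those of Tagln, Atf3, Nfkbiz and Cst6 do not.

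The gene lists fixed beforehand gave small shifts. Of 20 lists tested with camera at the preset correlation, 10 were called, 5 higher and 5 lower in the titled Il1b-KO libraries, and 0 were called with an estimated correlation or with fry. The strongest was the immediate early response, with a median log2 difference of -0.23 over 31 genes (camera adjusted p = 9.98e-05; adjusted p = 0.642 with an estimated correlation). Of its members 24 had a negative difference. By edgeR, 0 members passed over all genes and 1 adjusted over the list alone, while DESeq2 called Atf3 and Fosb over all genes. Fosb was at 196 ± 57 CPM against 398 ± 72.5, Jun at 481 ± 61.7 against 756 ± 144, and Fos at 625 ± 60.1 against 947 ± 255 (SD, n = 3 each). These genes respond to tissue dissociation as well as to growth signals. The heat shock list, whose members also respond to handling, had a median of -0.21 over 15 genes (camera adjusted p = 0.0178; adjusted p = 0.822 with an estimated correlation), with 1 member passing over the list alone. Dnajb1 in it was at 27.6 ± 2.12 against 41.1 ± 5.53.

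The list of genes that respond to IL-1 and NF-kB had a median log2 difference of -0.21 over 33 genes, 23 of them negative (camera adjusted p = 0.00604; adjusted p = 0.642 with an estimated correlation). Besides Nfkbiz, its genes of smallest p were Birc3, Irak3 and Csf1, with log2 differences of -0.46, -0.65 and -0.33. Complement genes had a median of -0.37 over 17 genes (camera adjusted p = 0.00866, and adjusted p = 0.642 with an estimated correlation). C3 was at 224 ± 51.7 against 440 ± 212 CPM. Cd59a, an inhibitor of the complement pore, went in the other direction at 9.08 ± 0.951 against 6.23 ± 0.193. In both lists, 0 members passed by edgeR over all genes and 0 adjusted over the list alone, while DESeq2 called Nfkbiz over all genes.

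Lists with higher values in the titled Il1b-KO libraries included interferon response, with a median log2 difference of 0.25 over 31 genes (camera adjusted p = 0.00735; adjusted p = 0.822 with an estimated correlation). Isg15 in it was at 71.4 ± 12.5 against 45.3 ± 3.51 CPM. The MHC class I and immunoproteasome genes had a median of 0.30 over 16 genes (camera adjusted p = 0.00389; adjusted p = 0.822 with an estimated correlation), with Tap1 at 18.4 ± 1.23 against 15 ± 0.404. The cytoskeleton and mechanical response list had a median of 0.15 over 19 genes (camera adjusted p = 0.0457; adjusted p = 0.642 with an estimated correlation). Tagln, which encodes an actin-binding protein of contractile cells, was at 297 ± 79.9 against 123 ± 47.9. The proliferation list had a median of 0.43 over 32 genes (camera adjusted p = 0.0201; adjusted p = 0.92 with an estimated correlation), and Tyms in it was at 44.6 ± 4.3 against 27 ± 8.39. In these 4 lists, 0 members passed by edgeR over all genes and 0 adjusted over the list alone, while DESeq2 called Tagln over all genes.

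Activated fibroblast genes had a median log2 difference of 0.40 over 25 genes, 23 of them positive (camera adjusted p = 0.00389; adjusted p = 0.92 with an estimated correlation). Acta2, smooth muscle actin, was at 123 ± 52.4 against 62 ± 20 CPM and Timp1 at 312 ± 113 against 164 ± 84.4, while Fap, fibroblast activation protein, was lower at 76.1 ± 5.54 against 108 ± 10.9. Resting fibroblast genes had a median of -0.38 over 20 genes (camera adjusted p = 0.0485, and adjusted p = 0.92 with an estimated correlation). The receptor gene Pdgfra was at 294 ± 48.3 against 458 ± 84.3. Mfap5 went in the other direction at 3203 ± 310 against 2229 ± 872. In both lists, 0 members passed by edgeR over all genes and 0 adjusted over the list alone. DESeq2 called Tagln, a member of the activated list, over all genes. The activated median was 0.14 without titled WT 2 and 0.23 without titled Il1b-KO 2, with the call lost in both (camera adjusted p = 0.193 and 0.35), and 0.68 without titled Il1b-KO 1 and 1.31 without titled WT 3. The resting median was 0.0031 without titled WT 2, -0.10 without titled Il1b-KO 2, -0.24 without titled WT 1 and -0.27 without titled Il1b-KO 3, with the call lost in each (camera adjusted p = 0.826, 0.909, 0.245 and 0.0555), and -0.58 without titled Il1b-KO 1 and -0.61 without titled WT 3.

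Leaving out 1 library ended the call of 9 of the 10 lists in at least 1 of the 6 fits, all but the immediate early response, whose median ranged from -0.15 to -0.43. The IL-1 and NF-kB list lost its call without titled WT 2 (median -0.11) and without titled Il1b-KO 2 (-0.12), as did complement (-0.20 and -0.26) and cytoskeleton (0.05 and 0.06), the latter also without titled Il1b-KO 3 (0.09). Heat shock lost it without titled WT 1 (-0.02) and titled Il1b-KO 2 (-0.11). Interferon response lost it without titled Il1b-KO 1 (0.12) and titled WT 3 (0.16), as did MHC class I (0.20 and 0.21). Proliferation lost it without titled WT 2 (0.17), titled WT 3 (0.13) and titled Il1b-KO 1, where its median changed sign to -0.23, and its median was 1.31 without titled WT 1. Without titled WT 2 or titled Il1b-KO 2, 5 lists were called.

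The remaining 10 lists were not called by camera. Their median log2 differences were 0.05 for collagens and matrix structure (the test's direction was down), 0.10 for matrix crosslinking and remodelling, 0.08 for TGF-beta response, -0.06 for the unfolded protein response, 0.06 for hypoxia and glycolysis, -0.13 for cholesterol synthesis, 0.07 for mitochondrially encoded genes, 0.10 for the Wnt pathway, 0.43 for bone and cartilage matrix genes and -0.03 for Y-linked genes (the test's direction was up). The X inactivation list had 0 tested genes. Cholesterol synthesis was called lower without titled WT 2 (median -0.36) and without titled Il1b-KO 2 (-0.75). Bone and cartilage matrix genes were called higher without titled Il1b-KO 1 (0.67), without titled WT 3 (1.33), with no count filter (0.69) and with the replicate block (0.62). Marker lists of other cell types were not called with all 6 libraries and the settings above. Their medians in fibroblast-like cells were 0.27 for macrophage-like, 0.17 for endothelial-like, 0.37 for mural-like, 0.08 for Schwann-like and -0.24 for cardiomyocyte-like markers (camera adjusted p from 0.0549 to 0.608), and 0.09 for fibroblast-like markers. The cardiomyocyte-like list lay next to the threshold and was called lower under 7 alternatives: without titled WT 1, without titled Il1b-KO 1, with no count filter, with the replicate block, in all kept cells, with no doublet removal and after thinning (adjusted p from 0.00533 to 0.0498). Macrophage-like markers were called higher without titled Il1b-KO 1 (0.0362), mural-like markers with the replicate block (0.0455) and epicardial or mesothelial-like markers in all kept cells (1.9e-06). The cardiomyocyte gene Myh6 was at 0.533 ± 0.283 against 1.44 ± 0.392 CPM. In fibroblast-like cells, neutrophil, T or NK cell, B cell, epicardial or mesothelial and erythroid markers had too few tested genes.

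**Figure D2:**
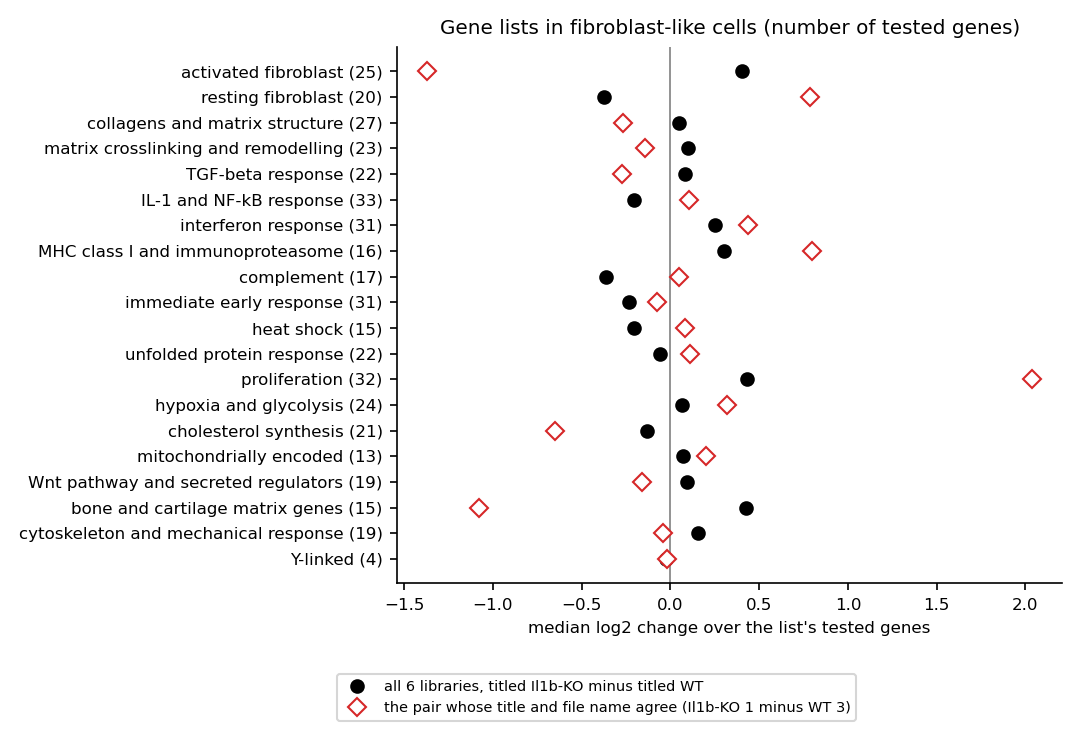
Median log2 difference of each gene list in fibroblast-like cells (x axis), with the number of tested genes in brackets, for titled Il1b-KO minus titled WT over all 6 libraries (filled circles) and for the pair of libraries whose title and file name agree (open diamonds). Activated fibroblast genes have a median of 0.40 in the first and -1.37 in the second.

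The share of fibroblast-like cells with a Postn UMI, at 2000 UMIs per cell, was 55.0%, 30.3% and 88.2% in the libraries titled WT 1, 2 and 3, and 62.1%, 91.1% and 73.1% in those titled Il1b-KO 1, 2 and 3. The means were 57.8% ± 29.0 and 75.4% ± 14.6 (SD, n = 3 each; exact permutation p = 0.4). The Meox1 shares were 40.4%, 23.02% and 65.0% in titled WT 1, 2 and 3, and 33.9%, 68.3% and 50.8% in titled Il1b-KO 1, 2 and 3, with means of 42.8% ± 21.1 and 51.0% ± 17.2 (SD, n = 3 each; exact permutation p = 0.7). Unthinned, the Postn shares ran from 41.9% to 96.2% and the Meox1 shares from 49.1% to 91.9%. Thinning left out 18 to 44 shallower cells per library. In endothelial-like cells of all libraries together, 9 of 115 thinned cells had a Postn UMI (7.83%, 95% Clopper-Pearson interval 3.64 to 14.3) and 32 of 115 a Meox1 UMI (27.8%, 19.9 to 37.0), at median depths of 5828 UMIs against 10518 in fibroblast-like cells before thinning. The Meox1 shares of the libraries titled WT 2 and Il1b-KO 1 lay within this pooled interval. Against the endothelial-like cells of the same library, which were only 10 to 28 thinned cells, they did so too (1 of 10, interval 0.253 to 44.5; 8 of 23, interval 16.4 to 57.3), as did that of titled WT 1 (4 of 13, interval 9.09 to 61.4). The Meox1 shares of titled WT 2 and Il1b-KO 1 thus cannot be told from those of endothelial-like cells. That of titled WT 1 (40.4%) lay above the pooled interval, and its 13 endothelial-like cells are too few to decide. Whether Meox1 UMIs in endothelial-like cells are background or expression was not tested. For both genes the libraries titled WT 3 and Il1b-KO 2 had the highest shares, and the difference between the titled groups was smaller than the SD of the titled WT libraries. Without titled WT 2 the differences were 3.85 percentage points for Postn and -1.69 for Meox1, in place of 17.6 and 8.2.

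The largest cluster of fibroblast-like cells was cluster 9 in the libraries titled WT 1 and WT 2, cluster 2 in those titled WT 3 and Il1b-KO 2 (25.2% and 20.3%), and cluster 0 in those titled Il1b-KO 1 and Il1b-KO 3 (31.1% and 19.6%). Cluster 0 held 15.9% in titled WT 1 and 3.17% to 5.15% in the remaining 3 libraries. Cluster 9 held 22.5%, 39.8% and 11.6% of these cells in the libraries titled WT 1, WT 2 and Il1b-KO 1, and 2.2%, 1.79% and 5.42% in those titled WT 3, Il1b-KO 2 and Il1b-KO 3. Cluster 4 held 0.0975%, 0.905% and 0.417% in the first 3 of these libraries and 17.2%, 16.3% and 16.9% in the other 3.

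The libraries titled WT 3 and Il1b-KO 1, whose titles and file names agree, allow a comparison of 1 library with 1, with no replicate check and no test. This comparison was added after the data were seen. Postn was at 1904 CPM in titled Il1b-KO 1 and 4920 in titled WT 3, and Meox1 at 308 and 741. Activated fibroblast genes had a median log2 ratio of -1.37 and bone and cartilage matrix genes one of -1.08. Resting fibroblast genes had a median of 0.79, proliferation genes 2.04, interferon response genes 0.44 and MHC class I and immunoproteasome genes 0.80. The IL-1 and NF-kB list had a median of 0.10. Of the 10 lists called over all 6 libraries, 6 had a median of opposite sign in this pair: activated fibroblast, resting fibroblast, IL-1 and NF-kB, complement (0.05), heat shock (0.08) and cytoskeleton (-0.04), of which the last 3 lay within 0.1 of 0. The interferon, MHC class I, proliferation and immediate early lists (-0.08 for the last) had the same sign in both.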

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

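No gene separated the titled groups by edgeR under any of the 14 other edgeR settings or by limma-voom, while DESeq2 called 31 genes. The count of called lists was 10 with camera at the preset correlation, 8 to 11 under the alternatives that kept all libraries and the preset, 5 to 8 when 1 library was left out (5 without titled WT 2 and without titled Il1b-KO 2), and 0 with an estimated correlation and 0 with fry, so the calls depend on the preset correlation. With all libraries and the preset, the resting fibroblast list lost its call with the other scaling (adjusted p = 0.0516), the stricter count filter (0.0703), all kept cells (0.0503) and thinning (0.0509), over a range of 0.0241 to 0.0703, and the cytoskeleton list in all kept cells (0.0632). The macrophage-like share differed by 0.0359 percentage points (titled Il1b-KO minus titled WT), with -0.0023 to 0.102 when 1 library was left out. The difference in the Meox1-positive share was 8.2 percentage points, with -1.69 (without titled WT 2) to 19.3, and that in the Postn-positive share was 17.6, with 3.85 (without titled WT 2) to 32.8 (without titled WT 3). The pair of libraries whose title and file name agree was chosen after seeing the data. In it these 3 differences were -0.0571, -31.1 and -26.1 percentage points, opposite in sign. Titled Il1b-KO 1 and WT 3 also lie on opposite sides of the first principal component (-33.6 and 44.2), which follows the file names as described below. The cause of the reversals was not tested, and a gene count could not be had from 1 library against 1. The Il1b and fibroblast-like share differences kept their sign under each alternative run. Among single genes, the log2 difference of Cx3cr1 was -0.0067 with the other scaling, -0.0072 with no count filter, -0.0088 by DESeq2, -0.0053 by limma-voom and -0.0901 to 0.134 without 1 library. Leaving out 1 library gave -0.11 to 0.83 for Meox1, -0.0450 to 1.31 for Postn and -0.127 to 0.05998 for Rela.

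With the titled replicate number as a block, 0 genes and 11 lists were called. The paired exact sign-flip p was 0.25 for Il1b, which is the smallest that 3 pairs can give, and 0.75 to 1.0 for the other values, whose differences are unchanged by construction. The correlations of same-numbered libraries did not show pairing (r = 0.57, -0.34 and 0.34), and not every library correlated best with its own number. Titled WT 3 correlated best with titled Il1b-KO 2 (r = 0.59), which is on its side of the file-name split. The correlations therefore cannot decide whether the numbers mark pairs. The Il1b comparison rests on 217 UMIs, but the counting intervals of the 3 libraries titled WT did not overlap, so the spread between libraries exceeds counting error there. In simulation, with genes drawn independently, 34% of 2-fold changes and 2% of 1.5-fold changes were recovered.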

Other observations

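The following describe biology outside the titled comparison, and of the tests given here only those of depth and of genes near Il1b and Cx3cr1 had their expected outcome written before the result was seen. For the splits, Il1b in macrophage-like cells, other cell types and the file-name numbers it was written afterwards, and for Il1b the criterion was then changed from the pooled counts to the values per library, which changed its reading. Cycling fibroblast-like cells, those in 2 clusters with histone or mitotic genes among their leading genes, chosen after the values were seen, made up 6.97% (95% interval 6.38 to 7.59) of fibroblast-like cells in the library titled Il1b-KO 1, 5.91% (5.28 to 6.59) in titled WT 1 and 3.64% (3.14 to 4.2) in titled Il1b-KO 3, against 1.06% to 1.31% in titled WT 2, WT 3 and Il1b-KO 2. Wdfy1, chosen after its values were seen, was at 16.9 and 17.0 CPM in fibroblast-like cells in titled Il1b-KO 1 and 3 and at 41.6 to 63.1 in the other 4 libraries. Ddx3y was at 114 to 126 CPM and Xist had at most 16 UMIs in each of the 6 libraries.

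The largest structure among the libraries follows the file names. The first principal component (53.2% of the variance) set the libraries titled WT 1, WT 2 and Il1b-KO 1, whose files are named for the deletion, apart from those titled WT 3, Il1b-KO 2 and Il1b-KO 3, whose files are named WT. The second (25.1%) ordered the libraries by title, at 10.4, 32.2 and 18.4 in titled WT 1, 2 and 3 and -35.3, 9.08 and -34.7 in titled Il1b-KO 1, 2 and 3, with titled Il1b-KO 2 next to titled WT 1. In the file-name split edgeR called 908 genes in fibroblast-like cells, 334 higher and 574 lower on the side named for the deletion, between 290 and 1143 when 1 library was left out (290 without titled Il1b-KO 2, 339 without titled WT 3, 351 without titled WT 1 and 497 without titled WT 2). Activated fibroblast genes had a median log2 difference of -1.36, with 17 of 25 called lower and 0 higher (20 lower adjusted over the list alone; camera adjusted p = 0.0258 with an estimated correlation). Among them were Postn (log2 difference -1.51, adjusted p = 0.0219) and Meox1 (-1.17, adjusted p = 0.0436). Cthrc1, a collagen triple helix repeat protein, was also called (log2 difference -4.28, adjusted p = 0.00302). So was the cartilage matrix protein gene Comp (-3.59, adjusted p = 0.00632). Cthrc1 and Comp were chosen from this list after their values were seen. Bone and cartilage matrix genes, which share Comp and Cilp with that list, had a median of -1.19, with 8 of 15 called lower (camera adjusted p = 0.0258 with an estimated correlation). Proliferation genes had a median of 1.34 over 32 genes, with 0 called (camera adjusted p = 3.82e-06; 0.483 with an estimated correlation). Resting fibroblast genes had a median of 0.85, with 7 of 20 called higher (camera adjusted p = 0.118 with an estimated correlation). The IL-1 and NF-kB list had a median of 0.32, with 5 of 33 called higher and 0 lower (camera adjusted p = 0.21 with an estimated correlation). Among markers of other cell types within the same cells, macrophage-like markers had a median of -0.79, with 0 of 11 called over all genes and 4 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0688, 0.341 with an estimated correlation; fry adjusted p = 0.0326). Endothelial-like markers had a median of -0.31 with 2 of 9 called lower, and 2 lower and 1 higher adjusted over the list alone. Mural-like markers had a median of -0.23 (2 called higher, 1 lower), cardiomyocyte-like 0.39 (1 higher, 1 lower) and Schwann-like 0.10 (1 lower). Camera called none of these lists. The genes of smallest p, named after their values were seen, were Col11a1 (log2 difference -4.87), Cpe (-3.03) and Nrg1 (-4.68) on the lower side and Necab1 (1.45) on the higher side.

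For the titled comparison, the 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. By edgeR the titled split called 0 genes, a number that all 10 reach by definition, so this count tests nothing. The highest other split called 908. The titled split called 10 lists, which 5 of the 10 splits reached, itself included, and the highest other called 14. A split that calls 908 genes where the titled one calls 0 points to a structure of the libraries other than that of the titles.

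A hypothesis for that structure is that titles and files were exchanged for 4 libraries, in which case the file-name split may be the genotype comparison. The splits are again too few for a share under 0.05, with 1 of 10 reaching 908 calls and 84 in the highest other. After thinning all libraries to the smallest total, 845 genes were called, so unequal totals were not needed for most of the calls. The totals of fibroblast-like cells ran only from 55154900 to 77925600 UMIs, so the thinning was slight. It was applied to summed counts and cannot speak to depth per cell. Cells named otherwise were not needed for the calls, since fibroblast-like cells alone called 908 genes and all kept cells 750. Fibroblast-like cells are 97.6% of kept cells, so this count cannot speak to RNA of other cells inside their barcodes. Some macrophage-like and endothelial-like markers, chosen after their values were seen, were rare in fibroblast-like cells. Lyz2 was at 0.38 CPM on the side named for the deletion against 0.905, Emcn at 0.151 against 0.737 and Flt1 at 0.837 against 2.14. Postn was at 1533 against 4357, which argues against RNA of such cells as the whole cause of the Postn difference. The mural-like marker Abcc9 went the other way, at 12.5, 16.4 and 8.96 CPM in titled WT 1, WT 2 and Il1b-KO 1. It was at 3.69, 4.89 and 3.24 in titled Il1b-KO 2, WT 3 and Il1b-KO 3. The endothelial-like marker Cav1 also went the other way, at 13.6, 14.8 and 18.9 CPM in titled WT 1, WT 2 and Il1b-KO 1. In titled Il1b-KO 2, WT 3 and Il1b-KO 3, Cav1 was at 12.6, 11.4 and 13.2. The macrophage-like list was lower on balance, 2 endothelial-like markers were called lower, and some mural-like, cardiomyocyte-like and Schwann-like markers were called too. A small share of RNA of these cells that differs between the sides therefore stays open.

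On the exchange itself, genes within 10 Mb of Il1b or Cx3cr1 were called at an odds ratio of 0.807 (95% interval 0.434 to 1.38). Il1b in macrophage-like cells was 3.65 times as high on the side named for the deletion (580 against 159 CPM, pooled; 95% interval 2.71 to 4.95, counting error only; 1.89 without titled WT 2 and 7.67 without titled Il1b-KO 2), the opposite of what a deletion that removes the counted part would give, and by the criterion first written this would argue against the exchange. The libraries of both sides overlapped only through titled Il1b-KO 1, with 0 UMIs in 2 macrophage-like cells, while titled WT 1 and WT 2 (325 and 839 CPM) lay above all 3 libraries of the other side (224, 137 and 35.6). Grouped by title, the same values were 325, 839 and 137 CPM in titled WT 1, 2 and 3. They were mostly lower in titled Il1b-KO 1, 2 and 3, at 0, 224 and 35.6, but titled Il1b-KO 2 lay above titled WT 3. The exchange is left open because 49 cells were counted in all and the deleted part is not given. A batch or another difference between hearts, such as how far remodelling had gone, that happens to follow the file names was not tested and stays open too.

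Libraries with the same number in their file names deviated from their side's mean together, with r = 0.20, 0.41 and 0.55 across genes for the 3 numbers, each the highest for both of its libraries. The mean, 0.385, was the highest of the 6 possible pairings, which are too few to exclude chance. With these numbers as a block, the file-name split called 2062 genes. If the numbers mark libraries prepared together or animals of 1 litter, which the labels do not say, the file names may carry the design, but this cannot be told apart from chance here.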
